A study of Mus musculus with 10 samples.

How the data were processed

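Messenger RNA of gastrocnemius muscle was sequenced from 10 samples of C57BL/6 mice, 5 labelled control and 5 labelled COPD. Per the labels' protocols, total RNA was extracted with Trizol, polyadenylated RNA was purified with oligo(dT) beads and fragmented, complementary DNA was primed with random hexamers, and the amplified products were circularized for sequencing. Each sample took its group and replicate number from its title. The labels give no sex, litter, batch or hour of collection.

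The authors deposited a table of expected counts per gene, named by gene symbol, and a table of TPM (abundance per transcript length, scaled to a common total) for the same 18025 genes. The expected counts are estimates that need not be whole, and 30.7% of the values were not whole numbers. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5 and the genome build mm9; they give no role or order for these tools. Whether the counting used the strand of the reads is not given in the sources used here. The reference annotation at hand was of another build (GRCm38, GENCODE M21), so no coordinates are printed, and it served only to list which tested genes have exons that overlap those of a named gene. That was so for 11 of the 76 genes that the naming rule took, all on the opposite strand (Cbx7, Col4a1, Col4a2, Cxcl10, Dap3, Dbp, Dusp1, Foxp3, Ndufb6, Slc1a1 and Slc5a6), and their values are uncertain to the extent that reads of both genes were not told apart.

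Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr, which left 12697, libraries were scaled by TMM, and COPD was compared with control by edgeR 4.0.16 (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are COPD over control. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values are TMM-scaled. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01 and adjustment over the 38 lists with at least 5 tested members, out of 42. Single measures per library were compared by two-sided exact permutation tests over all 252 relabelings, whose smallest p is 0.00794. R was version 4.3.3, and figures were drawn with matplotlib 3.10.9.

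The groups, tests, lists and alternatives were set before the data were examined. The rule for named genes was set then too. It took up to 12 genes per direction with the largest change past the threshold and a mean of at least 5 CPM, leaving out predicted and clone-named genes. Where fewer than 5 genes passed in a direction, it took up to 10 with the smallest p, as values. It took myokines past the threshold over all genes or over the list alone and 6 more, up to 4 members with the smallest p of each list that passed or held at least 2 called genes, and Fbxo32, Trim63, Mstn, Igf1, Ppargc1a, Myh4 and Myh7. A few genes are not reported here by name; they stay in all tests and counts except the search of single genes for libraries that stand apart. Alternatives were DESeq2 1.42.0, other scaling factors and filters, limma on log2(TPM + 1) and log2(TPM + 0.1), voom with sample weights, a block for the replicate number, covariates, leaving out each library and other list tests. After the data were seen, settings for the Y-linked counts, scaling by library size alone, a permutation test of list means and a list test with trends of gene length and level removed were added. A library counted as having Y-linked transcripts when Ddx3y, Eif2s3y and Kdm5d together reached 1 CPM. Uty was left out because part of its count stayed in libraries that lacked the other 3. All 5 controls had such transcripts, so in fits with a term for Y-linked counts COPD replicates 2 and 3 alone set the fold change.

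The procedure was tested on simulated data with the means, dispersions and library sizes of this comparison of 5 against 5 libraries. Genes were drawn independently and no library was set apart, so the recovered shares may not hold for the real data. There Ddit4 (log2 fold change 3.01, adjusted p = 0.0872) and Fosb (2.72, adjusted p = 0.0651) did not pass by edgeR over all 10 libraries. Among 12575 genes, edgeR recovered 24.6% of the genes changed by 1.5-fold, 84.1% of those changed 2-fold and 98.2% of those changed 4-fold, and 5.48% of its calls were unchanged genes. DESeq2, over 12697 genes, recovered 42.6%, 88.0% and 98.2%, and 16.8% of its calls were unchanged. Library totals of 14085854 to 17251034 counts make 1 CPM, before TMM scaling, stand for 14.1 to 17.3 counts, so that genes near 1 CPM carry few counts and large counting error. No pair of libraries agreed within sampling noise (chi-square per degree of freedom 16.9 to 115), so none was treated as a library deposited more than once; this does not show that samples came from separate animals.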

Results

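Gastrocnemius muscle, the large fast-twitch muscle of the calf, was profiled by messenger RNA sequencing in 10 samples of wild-type C57BL/6 mice, listed at 8 weeks of age. 5 samples came from control mice and 5 from mice with chronic obstructive pulmonary disease (COPD) modelled by cigarette smoke. The title of the series names myokines, the proteins that muscle secretes, as a question of the study. The labels do not say whether each sample came from its own animal, so that the p-values measure the spread between these samples. Expected counts were given for 18025 genes, and 12697 passed the filter on low counts. Library totals ran from 14085854 to 17251034 expected counts. Their mean was 16251028 ± 693567 in control and 15146010 ± 1232434 in COPD (SD, n = 5 each), a difference that did not pass the two-sided exact permutation test (p = 0.119). TMM scaling factors were 1.06 ± 0.0619 in control and 0.948 ± 0.0196 in COPD, and 11267 ± 129 and 10915 ± 227 genes had 1 TPM or more (SD, n = 5 each). Each of these measures differed between the groups (two-sided exact permutation p = 0.0159, adjusted p = 0.0476 over 6 library measures). Without COPD replicate 5, the other 4 COPD libraries differed from the controls by -1609412 counts in mean library total (exact permutation p = 0.00794).

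The most abundant transcripts were those of fast muscle, led by Atp2a1 (the calcium pump of the fast-fibre sarcoplasmic reticulum), the skeletal actin gene Acta1 and the fast myosin heavy chain gene Myh4. The 10 most abundant genes took 26.3 ± 3.19% of the counts in control and 29.1 ± 1.06% in COPD (SD, n = 5 each; two-sided exact permutation p = 0.0794). That difference passed when control replicate 3 was left out (3.93 percentage points, exact permutation p = 0.00794). Transcripts of the Y-linked genes Ddx3y, Eif2s3y and Kdm5d summed to between 1118 and 1974 counts in the 5 control libraries and in COPD replicates 2 and 3, and to 4, 3 and 3 counts in COPD replicates 1, 4 and 5. On the first principal component of log2 CPM (counts scaled to a common library total), the controls lay between -23.9 and -10.04 and COPD replicates 1 to 4 between 11.4 and 38.0, while COPD replicate 5 lay at -21.9 (two-sided exact permutation p = 0.0397, adjusted p = 0.0794 over the 6 library measures).

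The comparison of COPD with control asked which genes of the muscle differ in the disease model. Expression of 8 genes differed (adjusted p under 0.05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with 7 higher and 1 lower in COPD. DESeq2, over 17925 genes without the low-count filter, called 263 higher and 151 lower and voom with sample weights 86 and 51, all 8 genes among them in both. Each of the 8 separated all 5 COPD libraries from all 5 controls. Dbp, a transcription factor of the circadian output, fell from 136 ± 32.3 to 32.9 ± 10.9 CPM (SD, n = 5 each), a log2 fold change of -2.04 ± 0.22 (SE; adjusted p = 0.00924). Ercc5, an endonuclease of nucleotide excision repair, rose from 15.1 ± 1.68 to 30.6 ± 4.61 CPM (log2 fold change 1.02 ± 0.13, adjusted p = 0.0203). Trp53inp1, a p53-inducible gene, rose from 7.17 ± 0.886 to 13.1 ± 1.10 CPM (log2 fold change 0.87 ± 0.12, adjusted p = 0.0251). The lysine methyltransferase gene Mettl21e rose from 2.597 ± 0.789 to 8.04 ± 1.89 CPM (log2 fold change 1.63 ± 0.23, adjusted p = 0.0277). Slc1a1, a glutamate and cysteine transporter, rose from 2.94 ± 0.888 to 8.06 ± 1.62 CPM (log2 fold change 1.45 ± 0.22, adjusted p = 0.0362).

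The remaining 3 genes lay below the mean of 5 CPM set for naming. Foxp3 and Slc10a6 are named because of their values, and Npas2 as a member of the circadian list. Npas2, a partner of Arntl in the core clock, rose from 0.444 ± 0.0966 to 2.05 ± 0.777 CPM (log2 fold change 2.18 ± 0.34, adjusted p = 0.0425). Slc10a6, a transporter of sulfated steroids, rose from 2.61 ± 0.532 to 6.25 ± 1.12 CPM (log2 fold change 1.26 ± 0.18, adjusted p = 0.0301). Foxp3, the transcription factor of regulatory T cells, had the largest fold change of the 8, from 0.373 ± 0.0849 to 6.11 ± 3.04 CPM (log2 fold change 4.00 ± 0.52, adjusted p = 0.0225). It lay between 6.62 and 8.27 CPM in COPD replicates 1 to 4 and at 0.857 CPM in COPD replicate 5. Exons of Foxp3, Dbp and Slc1a1 overlap those of other tested genes on the opposite strand in the GRCm38 annotation. No source used here says whether the counting used strand, so their values are uncertain to that extent.

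**Figure D1:**
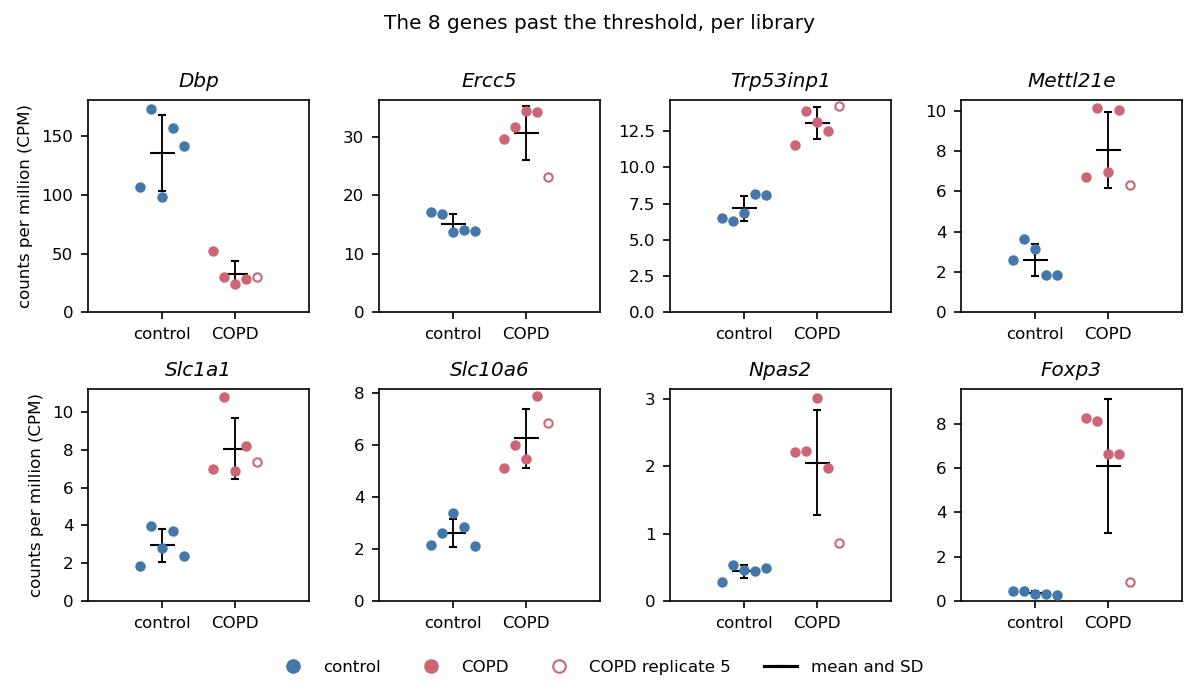
CPM (vertical axes, each from 0) of the 8 genes past the threshold in 5 control and 5 COPD libraries; points are libraries, the open point is COPD replicate 5, and black bars are the mean and SD. For Foxp3, COPD replicate 5 lies at 0.857 CPM and the other COPD libraries between 6.62 and 8.27 CPM.

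At an unadjusted p under 0.05, edgeR listed 1851 genes, 1008 higher and 843 lower, where 635 would be listed by chance if genes were independent. The groups did not overlap for 361 genes, 2.84% of those tested, against 0.794% by chance. Among lower genes other than Dbp, those with the smallest p did not pass the adjusted threshold. They were the drug efflux gene Abcb1b (log2 fold change -0.78 ± 0.13, adjusted p = 0.0520) and the vitamin transporter gene Slc5a6 (-0.66 ± 0.11, adjusted p = 0.0582). Further ones were the Polycomb gene Cbx7 (-0.59 ± 0.10, adjusted p = 0.0611) and the cholesterol efflux gene Abca1 (-0.81 ± 0.15, adjusted p = 0.0611). Dap3 (-0.76 ± 0.15) and Tap2 (-0.82 ± 0.16) had adjusted p of 0.0757 and 0.0780, and the clock gene Per3 (-1.26 ± 0.24) one of 0.0710. The count depended on COPD replicate 5. Without it, 263 genes were higher and 147 lower, all 8 genes among them. Leaving out COPD replicate 2 left 0 genes past edgeR's threshold (1510 at an unadjusted p under 0.05), and leaving out control replicates 1 to 5 in turn left 3, 3, 1, 1 and 2 genes and leaving out COPD replicate 4 left 5. With limma on log2(TPM + 1), which changes the unit, the test and the filter (11166 genes) together, the median of all tested genes was -0.18 on the log2 scale, and 12 genes were called higher and 111 lower. The same without a filter called 0 higher and 2 lower (3649 at an unadjusted p under 0.05). With upper-quartile scaling the split was 7 higher and 3 lower, and with library size alone 2 higher and 4 lower.

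Genes of the circadian clock moved in opposite directions. Of the 20 tested members of the list, 1 was higher and 1 lower over all genes tested, and 5 were higher and 6 lower when adjusted over the list alone. Higher were Npas2, its partner Arntl (log2 fold change 1.53 ± 0.37), Clock (0.58 ± 0.12), the repressor Nfil3 (1.25 ± 0.30) and Per1 (0.70 ± 0.17). Among the lower were Dbp, its relatives Hlf (-0.79 ± 0.26) and Tef (-0.30 ± 0.10), Per3 (-1.26 ± 0.24) and Nr1d2 (-0.38 ± 0.12). Because the members went both ways, the list did not pass the one-directional camera test (adjusted p = 0.421). Fry's mixed test, which asks whether the genes of a list change in either direction without comparing them with other genes, gave an adjusted p of 4.68e-05. A clock score was taken as the mean log2 CPM of Arntl, Npas2 and Clock minus that of Dbp, Per1, Per2, Nr1d1 and Nr1d2. It lay between -5.15 and -4.14 in the controls and between -3.09 and -2.16 in COPD, so that the 2 groups did not overlap. With that score as a covariate, edgeR called 0 genes (443 at an unadjusted p under 0.05). The score holds the called genes Npas2 and Dbp and parts the groups, so its term takes up the group difference by construction. The loss of calls therefore shows no cause. The labels give no hour of tissue collection.

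**Figure D2:**
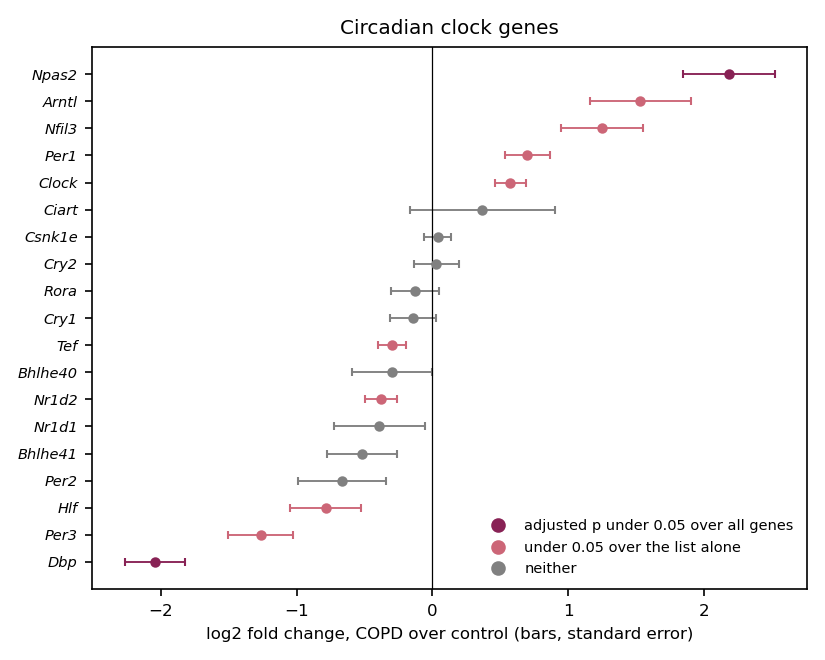
Log2 fold change of COPD over control (horizontal axis) for 19 of the 20 tested genes of the circadian list, with bars for the standard error; 5 libraries per group. Npas2, Arntl, Nfil3, Per1 and Clock lie above 0, and Dbp, Per3, Hlf, Nr1d2 and Tef below 0, each past the threshold adjusted over the list alone.

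Of the 57 myokine genes listed before the data were examined, 42 were tested, and 0 passed the threshold over all genes tested by edgeR (2 by DESeq2, which tested 56 of them without the filter), while 4 had an unadjusted p under 0.05. Adjusted over the list alone, 1 was higher and 1 lower. Adamts9, a secreted metalloproteinase, rose from 4.11 ± 1.61 to 17.8 ± 10.3 CPM (SD, n = 5 each; log2 fold change 2.12 ± 0.38, adjusted p over the list alone 0.00494, over all genes 0.0611). Csf1, the macrophage growth factor, fell from 14.1 ± 2.40 to 8.96 ± 1.201 CPM (log2 fold change -0.66 ± 0.14, adjusted p over the list alone 0.0128, over all genes 0.0887). The myokines with the next smallest p did not pass: Serpinf1 at a log2 fold change of 0.62 ± 0.23, Vegfa at 0.53 ± 0.19, Vegfb at 0.28 ± 0.14, Apln at 0.85 ± 0.41, Lgals1 at 0.56 ± 0.27 and Cxcl10 at -0.91 ± 0.46. Myostatin (Mstn), which restrains muscle growth, was at 43.8 ± 15.4 CPM in control and 46.0 ± 6.06 CPM in COPD (log2 fold change 0.07 ± 0.21, adjusted p = 0.911), and its sign changed with the scaling. The growth factor gene Igf1 was at 6.62 ± 1.21 and 9.33 ± 6.06 CPM (log2 fold change 0.49 ± 0.36, adjusted p = 0.571). Without COPD replicate 5, and over the libraries with Y-linked counts, 2 and 6 myokines passed over all genes tested. With a term for Y-linked counts 3 did by edgeR: Adamts9, Lgals1 (log2 fold change 1.13 ± 0.20, adjusted p = 0.0203) and Igf1 (1.22 ± 0.23, adjusted p = 0.0287). That fit rests on COPD replicates 2 and 3 against the controls. Igf1 was at 12.2 and 18.6 CPM in COPD replicates 2 and 3 and at 5.74 to 8.69 CPM in the controls. In COPD replicates 1, 4 and 5 it was at 6.50, 3.80 and 5.57 CPM.

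**Figure D3:**
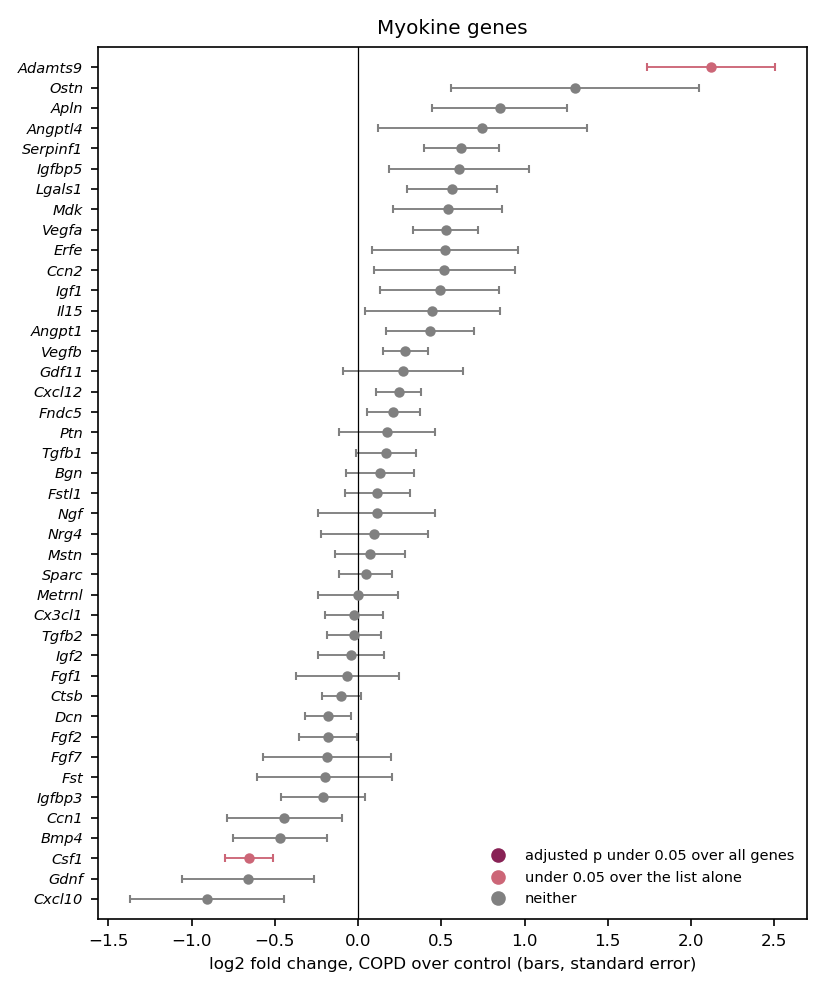
Log2 fold change of COPD over control (horizontal axis) for the 42 tested myokine genes, with bars for the standard error; 5 libraries per group. Adamts9 at 2.12 and Csf1 at -0.66 passed when adjusted over the list alone, and the other 40 did not.

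Of the 38 lists of pathways and cell type markers with at least 5 tested members, 12 passed limma's camera test with its preset correlation between genes, 9 higher and 3 lower. With an estimated correlation 0 of the 38 lists passed (4 at an unadjusted p under 0.05). An exact permutation test of each list's mean gave an unadjusted p under 0.05 for 7 lists and an adjusted p under 0.05 for 0. These 7 were among the 12. The tendon, macrophage, fatty acid oxidation, extracellular matrix and slow-fibre lists had unadjusted p from 0.0794 to 0.230.

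Interferon-response genes were lower as a group. Of 36 tested members, 35 had a log2 fold change below 0, with a median of -0.85, and 31 were lower when adjusted over the list alone. Over all genes tested 0 were by edgeR (31 at an unadjusted p under 0.05), 18 by DESeq2 and 11 by edgeR without COPD replicate 5. Among them were the antiviral genes Ifit1 (from 4.95 ± 2.69 to 1.81 ± 0.363 CPM) and Ifit3 (from 8.66 ± 3.502 to 3.53 ± 0.985 CPM). So were the RNA sensor gene Ifih1 (from 6.14 ± 1.03 to 3.43 ± 0.903 CPM) and Parp14 (from 14.6 ± 4.29 to 7.06 ± 1.99 CPM; SD, n = 5 each). Camera gave an adjusted p of 1.13e-20, against an adjusted p = 0.439 with an estimated correlation. The exact permutation test of the list mean gave p = 0.00794, the smallest that 5 against 5 libraries can give (adjusted p = 0.101). The glucocorticoid and fast-fibre lists had the same p. Centred on all 10 libraries, the list mean was 0.97 and 0.89 log2 CPM in control replicates 2 and 3 and 0.19, 0.21 and -0.08 in control replicates 1, 4 and 5, against -0.13 in COPD replicate 5 and -0.75 to -0.36 in the other COPD libraries. Genes of MHC class II were also high in control replicates 2 and 3 (0.58 and 0.54). The macrophage list was lower by camera (adjusted p = 0.00141, and adjusted p = 0.778 with an estimated correlation), with 11 of 12 members below 0. When adjusted over the list alone, 0 were past the threshold. Its mean, centred in the same way, was -1.15 and -0.72 log2 CPM in COPD replicates 2 and 3. COPD replicates 1, 4 and 5, at -0.09, -0.06 and 0.60, lay inside the range of the controls (-0.24 to 0.63). Its complement genes C1qa, C1qb and C1qc had log2 fold changes of -0.63 ± 0.28, -0.69 ± 0.31 and -0.61 ± 0.27, and the lysozyme gene Lyz2 of -0.71 ± 0.31. Without COPD replicate 5, 28 interferon-response genes and 3 macrophage genes were lower when adjusted over the list alone. With a term for Y-linked counts, which leaves COPD replicates 2 and 3 against the controls, 24 and 10 were.

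Immediate early genes and genes that respond to glucocorticoids were higher as groups. Of 25 tested immediate early genes, 13 were higher and 0 lower when adjusted over the list alone, with a median log2 fold change of 0.84 (camera adjusted p = 6.93e-08; adjusted p = 0.439 with an estimated correlation). Fosb, a subunit of the AP-1 transcription factor, rose from 2.57 ± 1.60 to 16.9 ± 8.78 CPM and Maff from 4.69 ± 0.985 to 23.1 ± 11.2 CPM. Zfp36, which destabilizes messenger RNA, rose from 23.2 ± 1.66 to 83.5 ± 52.7 CPM and the phosphatase gene Dusp1 from 58.5 ± 11.6 to 108 ± 28.6 CPM (SD, n = 5 each). Of 22 glucocorticoid-responsive genes, 10 were higher and 1 lower when adjusted over the list alone, with a median of 0.79 (camera adjusted p = 1.00e-07; adjusted p = 0.246 with an estimated correlation). Ddit4, an inhibitor of mTORC1, rose from 12.7 ± 5.28 to 102 ± 83.5 CPM, with 219 CPM in COPD replicate 2 and 13.3 CPM in COPD replicate 5. Arrdc2 rose from 95.6 ± 15.0 to 243 ± 91.0 CPM and Tsc22d3 from 158 ± 40.5 to 312 ± 79.1 CPM. The mean log2 CPM of both lists in COPD replicate 5 lay below that of the other 4 COPD libraries.

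Genes of atrophy and the ubiquitin-proteasome system went both ways. Of 34 tested, 8 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00577, higher; adjusted p = 0.538 with an estimated correlation). Trim63, the muscle ubiquitin ligase MuRF1, rose from 124 ± 42.4 to 424 ± 250.4 CPM (SD, n = 5 each; log2 fold change 1.78 ± 0.45, adjusted p over all genes 0.107), with 93.9 CPM in COPD replicate 5. The other classical atrophy ligase gene, Fbxo32, did not pass, at 195 ± 99.3 and 311 ± 191 CPM (log2 fold change 0.67 ± 0.46, adjusted p = 0.543). The cell cycle inhibitor gene Cdkn1a (log2 fold change 1.36 ± 0.34) and the transcription factor gene Klf15 (0.83 ± 0.19) were higher, and the translation repressor gene Eif4ebp1 was lower (-1.10 ± 0.24), when adjusted over the list alone. Ddit4, Klf15, Cdkn1a and Trim63 are also members of the glucocorticoid list, so the 2 lists are not independent. With a term for Y-linked counts, 3 genes of the list were higher, and the median log2 fold change was 0.16 (0.14 without the term).

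Genes of energy metabolism and of fast fibres were slightly higher as groups. Of 73 tested genes of oxidative phosphorylation, 71 had a log2 fold change above 0, with a median of 0.31, and 15 were higher when adjusted over the list alone (camera adjusted p = 3.15e-21; adjusted p = 0.538 with an estimated correlation). Ndufc2, a subunit of complex I, rose from 95.9 ± 10.4 to 131 ± 11.2 CPM, and the other complex I genes Ndufb10, Ndufb6 and Ndufs8 had log2 fold changes of 0.40 ± 0.10, 0.36 ± 0.10 and 0.49 ± 0.14. Without COPD replicate 5, 58 members were higher when adjusted over the list alone. With a term for Y-linked counts 0 were, at a median log2 fold change of 0.37, and over the libraries with Y-linked counts 27 were, at a median of 0.38. In the list of glycolysis and glycogen, 3 genes were higher and 1 lower of 26 when adjusted over the list alone, and 0 passed over all genes by edgeR (camera adjusted p = 0.000176, higher; adjusted p = 0.439 with an estimated correlation). They were Ppp1r3c, which directs protein phosphatase to glycogen (from 456 ± 110 to 889.7 ± 145 CPM), the muscle enolase gene Eno3 (log2 fold change 0.53 ± 0.13), Pgam2 (0.69 ± 0.17) and, lower, the glycogenin gene Gyg (-0.59 ± 0.13). Of 33 genes of fatty acid oxidation and PPAR targets, 1 was higher when adjusted over the list alone, the lipid droplet gene Plin5 (log2 fold change 1.77 ± 0.42). Over all genes 0 passed by edgeR. The list was higher by camera (adjusted p = 0.00131; adjusted p = 0.778 with an estimated correlation), and its members Ucp3 (1.79 ± 0.57), Mlycd (0.64 ± 0.20) and Acot2 (1.24 ± 0.46) did not pass. In the lists of glycolysis and of fatty acid oxidation, 6 genes each were higher when adjusted over the list alone and COPD replicate 5 was left out. The coactivator gene Ppargc1a, which drives mitochondrial biogenesis, was at 43.1 ± 12.1 and 57.8 ± 41.3 CPM (log2 fold change 0.42 ± 0.41, adjusted p = 0.684), and its sign changed in one scaling of TPM.

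Of 17 fast-fibre genes, 5 were higher when adjusted over the list alone, among them Eno3, Myoz3 (log2 fold change 0.53 ± 0.16), Tpm1 (0.71 ± 0.22) and the myosin light chain gene Myl1 (0.62 ± 0.21), with a median of 0.29 (camera adjusted p = 1.34e-05; adjusted p = 0.538 with an estimated correlation). Myh4 itself did not pass (0.29 ± 0.20, adjusted p = 0.529). Adjusted over the list alone, 2 fast-fibre genes were higher without COPD replicate 5, at a median of 0.28. With a term for Y-linked counts 0 fast-fibre genes passed when adjusted over the list alone, at a median log2 fold change of 0.40. The slow-fibre list was lower by camera (adjusted p = 0.0145; adjusted p = 0.778 with an estimated correlation), with 13 of 15 members below 0 and 0 past the threshold when adjusted over the list alone. With a term for Y-linked counts, 2 slow-fibre genes were lower when adjusted over the list alone, at a median log2 fold change of -1.64 (-0.81 without the term). Members of the slow-fibre list were uneven among the controls. Myh7, the slow myosin heavy chain, was at 319 CPM in control replicate 1, 180 CPM in control replicate 4 and between 28.6 and 29.9 CPM in the other 3 controls. It was at 2.28 to 96.8 CPM in COPD (log2 fold change -1.88 ± 0.89, adjusted p = 0.354). Tnni1, Tnnt1 and Tpm3 had log2 fold changes of -1.70 ± 0.71, -1.43 ± 0.63 and -0.81 ± 0.31 and did not pass.

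Markers of tendon were higher by camera (adjusted p = 0.000196, and adjusted p = 0.627 with an estimated correlation). Of 11 tested, 5 were past the threshold when adjusted over the list alone, and the median log2 fold change was 1.18. The groups overlapped in the list mean (two-sided exact permutation p = 0.0794). Centred on all 10 libraries, it was -1.79 log2 CPM in control replicate 2 and -0.60 to 0.40 in the other controls, against -0.43 to 1.49 in COPD. Thbs4, a thrombospondin of tendon and muscle matrix, rose from 28.6 ± 6.94 to 64.9 ± 18.2 CPM (SD, n = 5 each). The tenomodulin gene Tnmd (log2 fold change 2.01 ± 0.59), Kera (1.44 ± 0.53) and Col11a1 (1.39 ± 0.51) were higher at means under 2 CPM over the 10 libraries. The extracellular matrix list, which moved with them, was also higher by camera (adjusted p = 0.00141; adjusted p = 0.778 with an estimated correlation), with 2 of 37 genes past the threshold when adjusted over the list alone, the basement membrane genes Col4a2 (log2 fold change 0.88 ± 0.19) and Col4a1 (0.98 ± 0.24). Its members Col14a1 (-0.73 ± 0.22) and Col8a1 (-0.67 ± 0.22) had values below 0 and did not pass. When COPD replicate 5 was left out, 3 tendon genes were higher when adjusted over the list alone, and 5 matrix genes were higher and 1 lower. With a term for Y-linked counts, 2 tendon genes were higher (median log2 fold change 0.87), and 0 matrix genes were higher and 2 lower (median 0.16, against 0.27 without the term).

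**Figure D4:**
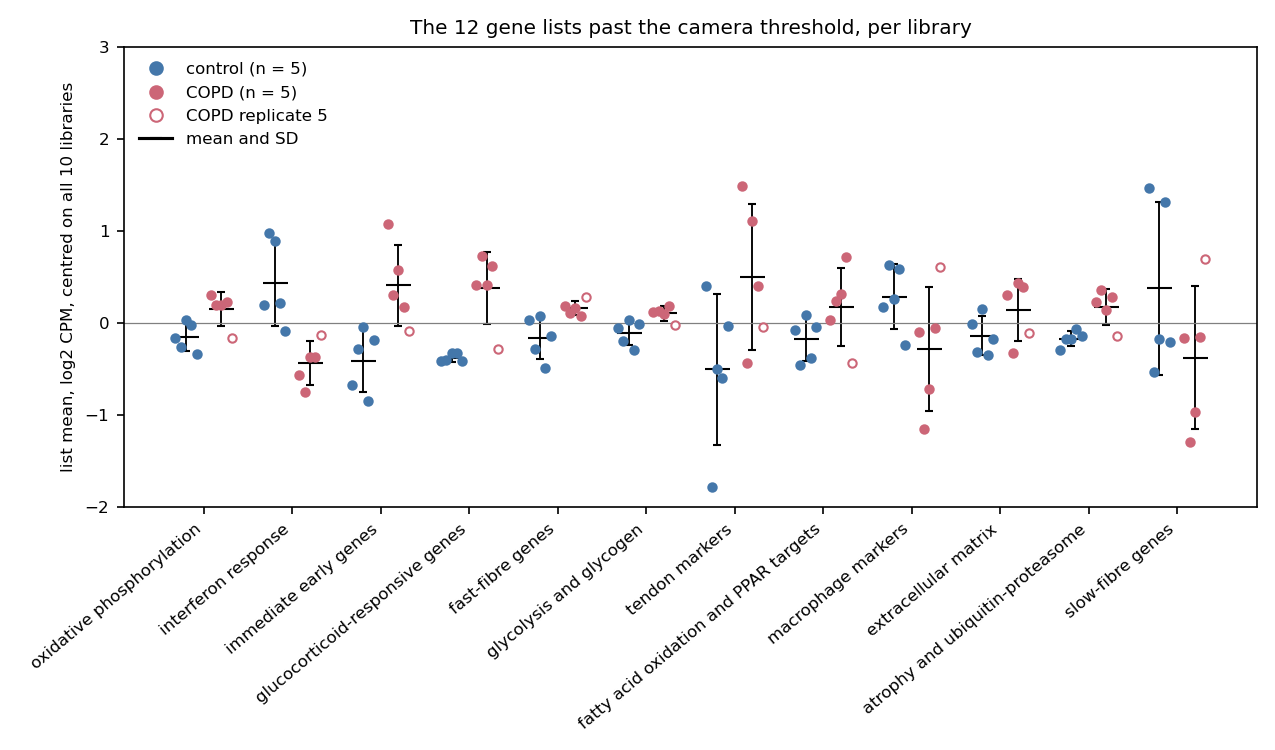
Mean log2 CPM of the members of the 12 lists past the camera threshold (vertical axis, each list centred on its mean over the 10 libraries), per library; filled points are libraries, the open point is COPD replicate 5, and black bars are the group mean and SD. The interferon list averaged 0.44 in control and -0.44 in COPD, and the glucocorticoid list -0.38 and 0.38.

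The other 26 lists with enough members did not pass the camera test, with adjusted p from 0.344 for myokines to 0.965. Markers of adipocytes, endothelium, Schwann cells, satellite cells, fibroblasts, smooth muscle, red cells and neutrophils and genes of MHC class II were among them. The neutrophil list had all 6 tested members below 0, with a median log2 fold change of -1.33. Its mean log2 CPM was 4.71 in control replicate 1 and between 0.66 and 1.48 in the other 4 controls. Without COPD replicate 5, which had the highest mean of the COPD libraries, the median was -2.69 and 4 of the 6 were lower when adjusted over the list alone. Markers of T, NK and B cells, of brown fat and of keratinocytes had 1, 2 and 3 tested members, and the genes encoded in mitochondria 0, too few for a list test.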

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

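The tests of COPD replicate 5, of the Y-linked counts and of Foxp3 and the count of splits for myokines adjusted over the list alone were chosen after the results were seen; the other counts over splits of the libraries were planned. In each group of 5 libraries, every named gene, list mean and library measure was searched for a library set apart from the other 4 by most of the group's range (Dixon's test at 95%). Of 228 such groups 9 stood out, and chance alone marks about 1 in 20. COPD replicate 5 was the library apart in 5 of the 9. It had 0.857 CPM of Foxp3 (others 6.62 to 8.27), 4.78 CPM of Maff (others 21.97 to 33.3), 249.99 CPM of Ndufb10 (others 308 to 320.2), 127 CPM of Ndufs8 (others 187 to 202) and a mean of 8.15 log2 CPM over oxidative phosphorylation genes (others 8.51 to 8.62). COPD replicate 1 stood apart for Dbp at 51.9 CPM (others 24.4 to 30.2) and COPD replicate 2 for Cxcl10 at 2.29 CPM (others 0.66 to 0.81). Control replicate 3 stood apart for Col4a2 at 107 CPM (others 69.9 to 78.3), and control replicate 1 for the neutrophil list at a mean of 4.71 log2 CPM (others 0.66 to 1.48).

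COPD replicate 5 lay near the controls. Over the 400 genes with the smallest p in a fit without it, its median position between the mean of the controls (0) and of the other COPD libraries (1) was 0.14, inside the range of controls held out in the same way (-0.01 to 0.30) and below COPD replicates 1 to 4 held out likewise (0.54 to 0.94). A control library with the wrong label would give such a position, and so may an animal with little response, which was not tested. Against a wrong label stand its clock score of -3.09, above all 5 controls (-5.15 to -4.14), and its 3 Y-linked counts where every control had at least 1441; neither excludes it, since hours of collection and sexes are not given. The lack of Y-linked transcripts is not enough to explain the position, since COPD replicates 1 and 4 lack them too and lay at 0.53 and 0.43 on the axis from the controls to COPD replicates 2 and 3, with replicate 5 at 0.05.

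The groups differ in Y-linked transcripts, which 3 COPD libraries lack and all 5 controls have, so a difference in sex might give differences between the groups. With a term for Y-linked counts, 8 of 8 called genes kept their direction and at least 0.5 of their log2 fold change (from 89.7% for Slc10a6 to 116% for Npas2). All 8 stayed past the threshold. Their direction was fixed beforehand, since each of the 8 separated all COPD libraries from all controls. Large sizes were favoured beforehand too, since the 8 were called on libraries that include COPD replicates 2 and 3. Those replicates have Y-linked counts like the controls and yet differ from them in the 8 genes. In them the difference does not go with Y-linked counts, and the kept sizes add little to that. Of the 12 lists past the camera threshold, 11 kept their direction and threshold with that term. This does not decide on sex, since the lists were called on the same libraries. Camera with its preset correlation also passed a median of 9 lists over other splits of the libraries. The term leaves the contrast to rest on COPD replicates 2 and 3 against the controls. It cannot tell how much of the difference in COPD replicates 1, 4 and 5 goes with sex. The disease model, an hour of collection and other handling that followed the groups stay open for these genes and lists.

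Foxp3 was at 90.0 to 111.8 expected counts in COPD replicates 1 to 4 and at 4.53 to 8.22 in the controls. Regulatory T cells as the source were argued against, since Cd3e, Cd3d, Cd3g and Cd4 together reached at most 0.0805 of the Foxp3 count in those libraries (at most 9 counts). Ccdc22, like Ppp1r3f, overlaps Foxp3 on the opposite strand. A transfer of its reads at an unchanged output of Ccdc22 would have lowered it by the 7.04 CPM that Foxp3 gained. That was argued against, since Ccdc22 was 3.68 CPM above the control mean in the 4 libraries (control SD 2.53). A higher output of Ccdc22 with part of its reads counted for Foxp3 would raise both genes, so the test does not decide on that. Ppp1r3f, whose reads may be shared with Foxp3 in the same way, fell by 3.19 CPM on average in those libraries (log2 fold change -1.41 ± 0.21, adjusted p = 0.00729 by edgeR without COPD replicate 5; -1.02 ± 0.29, adjusted p = 0.144 with it). Yet the sum of Foxp3 and Ppp1r3f was at least 8.09 CPM in each of the 4, above the highest control at 6.77 CPM, so reads moved from Ppp1r3f cannot be the whole gain. Transcription from this region in another cell type, or a difference in the animals' genomes, may be candidates and were not tested.

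Among 100 of the 126 splits of the 10 libraries into 5 and 5, 2 gave at least the 8 genes of the real one, the real one included. The highest other gave 10. For the count of genes chance is unlikely at that level, yet it is not excluded. That other split exchanged control replicate 3 and COPD replicate 5. For genes at an unadjusted p under 0.05, 4 of the 100 gave at least the 1851 of the real one, and the highest other gave 2183. The 3 others each exchanged 1 control library with COPD replicate 5. For gene lists chance stays open: 29 of the 100 splits gave at least the 12 lists of the real one. The highest other gave 21, and the median of the others was 9. For the 2 myokines past the threshold adjusted over the list alone chance stays open too: 8 of the 100 splits gave at least 2. The highest other gave 5. Over all genes tested the real split gave 0 myokines, a count that all 100 splits reach (highest other 0), so the splits say nothing of it.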

How the results depend on the processing

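Settings for the Y-linked counts, scaling by library size alone, the permutation test of list means and the list test with length and level trends removed were chosen after seeing the data. The main counts were 7 genes higher and 1 lower. They were 263 and 151 with DESeq2, 86 and 51 with voom and sample weights, 33 and 11 with the adipocyte score as covariate, 14 and 3 without a low-count filter, 4 and 3 with at least 5 CPM in 5 libraries (fewer genes tested), 12 and 111 with limma on log2(TPM + 1), 12 and 90 on log2(TPM + 0.1), 0 and 2 on log2(TPM + 1) without a filter, 2 and 4 with library size alone, 165 and 51 with Y-linked counts as a covariate, 336 and 152 over the 7 libraries with Y-linked counts, 0 and 1 with the slow-fibre score and 0 and 0 with the clock score as covariate. Upper-quartile factors gave 3 lower genes. Leaving out 1 library gave 0 to 263 higher and 0 to 147 lower genes; without each control in turn 0 to 2 genes were higher, and without COPD replicate 2 none passed. The clock score parts the groups without overlap, so its term takes up the group difference by construction; apart from that and the smaller sets of genes or libraries, the cause was not tested. The 8 genes kept their direction in every fit with all 8 tested. Library size alone moved the median of all genes to -0.17 and the TPM scales to between -0.21 and -0.17 on the log2 scale, so calls there lean to the lower side. The fit with the replicate number as a block called 7 genes (6 higher, 1 lower), 3 of them among the 8. Same-numbered libraries had correlations of -0.14 to 0.04, and no control correlated best with the COPD library of its own number. No pairing by number was seen, which does not exclude a weak one.

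Myokines past the threshold over all genes, 0 in the main test, were 2 with DESeq2, 1 without a low-count filter, 1 on log2(TPM + 1), 2 on log2(TPM + 0.1), 1 with voom, 1 with the adipocyte score, 3 with Y-linked counts as a covariate, 6 over libraries with Y-linked counts and 0 to 2 on leaving out 1 library. Adjusted over the list alone they were 2 in the main test, 0 with the clock score and 8 and 9 in the settings of Y-linked counts. The 12 gene lists became 0 with an estimated correlation and 0 with the permutation test of list means. Fry's directional test left 1, the glucocorticoid list (adjusted p = 0.0366). Fry's mixed test gave 14, 7 of them among the 12 and 7 others. The remaining list settings gave 10 to 12, and 11 of the 12 passed after trends of gene length and level were removed. The difference in library size was -1609412 counts without COPD replicate 5, and on leaving out any 1 library it lay between that and -839978. The difference in the share of the 10 most abundant genes was 3.93 points without control replicate 3, with a range of 1.71 to 3.93.

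Of the settings for log2 fold changes of the 76 genes that the naming rule took, 1624 kept direction and side of the threshold, 205 moved past it, 82 lost it and 42 changed sign, none of them a call of the main test. With the clock score as covariate the sign changed for Per3 (0.41), Vegfa (-0.31), Vegfb (-0.17), Lgals1 (-0.66), Tpm3 (0.039), Tnni1 (0.76), Tnnt1 (0.55), Myh7 (1.204), Myoz3 (-0.15), Myl1 (-0.46), Ndufs8 (-0.13), Plin5 (-0.34), Ucp3 (-1.65), Mlycd (-0.38), Acot2 (-2.50), Ppp1r3c (-0.016), Pgam2 (-0.036), Parp14 (0.0077), C1qa (1.18), C1qc (1.33), Lyz2 (1.07), C1qb (1.70), Col11a1 (-0.29), Fbxo32 (-2.49), Trim63 (-0.82), Igf1 (-1.12), Ppargc1a (-1.05) and Myh4 (-0.083). Apln was at -0.29 with Y-linked counts as a covariate and -0.28 over libraries that have them. Fbxo32 was at -0.14 with the slow-fibre score, and Ppargc1a at -0.0236 on log2(TPM + 0.1), and it ran from -0.0800 (without COPD replicate 4) to 0.66 on leaving out 1 library. Mstn, near 0 throughout, was at -0.0718 on log2(TPM + 1) with and without the filter, -0.0716 on log2(TPM + 0.1), -0.00392 with the slow-fibre score, -0.0892 with Y-linked counts as a covariate, -0.0802 over libraries that have them and -0.0880 with library size alone. On leaving out 1 library it ran from -0.0537 to 0.25, below 0 without control replicate 3 or 4. The sign changes with the clock score say little of the genes, since that score parts the groups without overlap. For the other sign changes the cause was not tested. At this depth 1.5-fold changes were mostly missed on simulated data (24.6% recovered by edgeR).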

Other observations

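The genes and tests of this part were chosen after the data were seen. In each of 3 fits, without COPD replicate 5, with a term for Y-linked counts and over the libraries with Y-linked counts, 82 genes passed edgeR's adjusted threshold in the same direction, 65 higher and 17 lower in COPD. The 3 fits share the 5 controls and COPD replicates 2 and 3, and of the 216 genes called with the term 215 were also called over the libraries with Y-linked counts, so that they are not independent and their agreement adds little. Values here are from the fit without COPD replicate 5 (5 control and 4 COPD libraries). Over all 10 libraries none of the genes named in this paragraph passed by edgeR, with adjusted p from 0.0520 for Bcl2l1 to 0.216 for Irs2. Higher were the AP-1 genes Fosb (log2 fold change 2.88 ± 0.51, SE) and Junb (2.61 ± 0.45), the small Maf gene Maff (2.56 ± 0.18), and Sik1, a kinase induced by cyclic AMP (2.09 ± 0.17, adjusted p = 0.000205). Irs1 (1.07 ± 0.18) and Irs2 (1.79 ± 0.43), adaptors of the insulin receptor, and the mTORC1 inhibitor Ddit4 (3.29 ± 0.47) were among them. So were the survival gene Bcl2l1 (1.14 ± 0.13), the creatine synthesis gene Gamt (1.60 ± 0.28), the nicotinamide riboside kinase gene Nmrk2 (2.02 ± 0.45) and the lactate transporter gene Slc16a3 (0.74 ± 0.14). Lower were the interferon-inducible genes Gbp9 (-1.72 ± 0.18) and Psmb8 (-1.14 ± 0.27), the epoxide hydrolase gene Ephx1 (-0.81 ± 0.17) and the methyltransferase gene Inmt (-0.96 ± 0.15). The list of insulin, IGF and mTOR signalling as a whole did not pass camera over all 10 libraries (adjusted p = 0.781), and without COPD replicate 5 its 30 members had a median log2 fold change of 0.04.

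The term for Y-linked counts itself passed the adjusted threshold of edgeR for 44 genes, 40 lower and 4 higher without Y-linked counts. The lower ones include Ddx3y, Eif2s3y and Kdm5d, which define the term and so pass by construction, and the Y-linked gene Uty. All libraries without Y-linked counts belong to the COPD group, so after allowing for the group the term rests on COPD replicates 1, 4 and 5 against COPD replicates 2 and 3. For Amd1, Odc1, Slc30a2, C7, Itga9, Grb10 and Igf1, COPD replicates 2 and 3 lay outside the range of the controls. Amd1 and Odc1, the rate-limiting enzymes of polyamine synthesis, had terms of -3.61 ± 0.40 (SE, log2; adjusted p = 0.00195) and -2.47 ± 0.26 (adjusted p = 0.00122). Amd1 was at 1747 and 1391 CPM in COPD replicates 2 and 3, between 96.5 and 342 CPM in the 5 controls and at 127, 161 and 97.7 CPM in COPD replicates 1, 4 and 5. Odc1 was at 323 and 309.9 CPM in COPD replicates 2 and 3, between 59.4 and 126 CPM in the controls and at 56.5, 60.1 and 54.4 CPM in COPD replicates 1, 4 and 5. For several genes COPD replicates 1, 4 and 5 lay outside the range of the controls too, on the other side. The zinc transporter gene Slc30a2 (-3.75 ± 0.39) was at 31.1 and 34.6 CPM in COPD replicates 2 and 3, 3.61 to 9.99 CPM in the controls and 1.99, 2.92 and 2.39 CPM in COPD replicates 1, 4 and 5. The complement gene C7 (-3.40 ± 0.29) was, in the same order, at 19.8 and 18.5, 4.68 to 5.80, and 1.77, 2.71 and 0.98 CPM. Itga9, an integrin gene (1.66 ± 0.25), was at 2.81 and 3.31, 5.72 to 7.17, and 7.46, 9.02 and 12.6 CPM. Grb10 (0.81 ± 0.14) was at 27.2 and 28.96, 32.3 to 40.9, and 49.7, 48.0 and 50.02 CPM. Igf1 (-1.54 ± 0.26) was at 12.2 and 18.6, 5.74 to 8.69, and 6.50, 3.80 and 5.57 CPM, with COPD replicate 1 inside the range of the controls.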
